A study of Mus musculus with 2 samples.

How the data were processed

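RNA sequencing was done on macrophages collected from infarcted hearts of C57BL/6 mice, with 1 library of Ly6Chi and 1 library of Ly6Clo cells collected on day 3 after coronary ligation. Per the labels' protocols, total RNA was purified with a column kit and libraries were made by standard Illumina methods. Per the submitters' processing notes, CASAVA 1.8.2 and TopHat were used, with the mouse build mm10. The counting program, the gene annotation, strand handling and the program that gave the statistic are not given in the sources used here.

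The authors deposited a single table for the series, with a gene symbol, 2 columns of whole numbers with 1 for each library, a signed statistic and a ranking. The statistic is a score per gene with no stated unit, deposited by the authors to compare the libraries, and the ranking orders genes by its size, per the file headers. The rank was recomputed from the size of the statistic with ties averaged, and it matched the deposited rank to within 1e-06 for 23284 of 23284 genes. The table's name carries the letters WAD, which match the abbreviation of the weighted average difference, a statistic that scales a log ratio by relative expression level. No header or label states this, so the score is not read as a fold change. If it is weighted in that way, genes of low abundance have small scores whatever their ratio.

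The 2 columns of values per library were not used in any result, because their codes match no label of either sample. Column order, the name of the table and expression of Ly6c2 were not taken as grounds for assigning them. Library totals, fold changes, counting intervals and the planned count of genes 2-fold apart were therefore not computed. For the same reason the planned matching of random lists on expression, the planned minimum value of 10 for named genes and the choice of other-cell markers by abundance could not be applied.

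Before the data were examined, 38 gene lists, 20 anchor genes and a rule for naming genes were fixed. Named genes were the anchor genes, the 12 largest statistics on each side among genes with a proper symbol, up to 4 list members with the largest size, and up to 3 members of each list of another cell type. In place of expression level, the size of the statistic chose the last group. Chil4, Ccl2, Ccl7, Cxcl5, H2-DMa, Itgax, Flt3, Zbtb46, Txk, Pdgfra and Ddx3y fall outside this rule and were named after their values were seen. The same holds for the genes of the families picked by symbol (Rps4x, Ctsd, Atp6v1h, Atp6v1c1 and Atp6v0d2). Values of a few genes that the rule names are not reported here. Members were matched by symbol or by an older symbol. Symbols were compared with the RefSeq annotation of GRCm38.p6, the same assembly as mm10, from which coordinates were taken: 20723 symbols were current, 2291 matched through a single synonym and 270 did not match. Older symbols are given where the table uses them.

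For each list, the median statistic of members with a value other than 0 was set against 10000 random lists of the same size drawn from all genes with a value other than 0, and its percentile was reported for lists of at least 3 such members. Percentiles at or above 97.5 or at or below 2.5 were taken as outside the band. The procedure was tested on simulated data, in which lists of 15 genes were drawn from 16302 shuffled statistics. It put 5% of 1000 unshifted lists outside the band, 45.5% of 200 lists shifted by 0.1, and 100% of 200 lists shifted by 0.3 in either direction. The simulated and random lists came from the same statistics, so the 5% follows from the bounds and checks only the computation. Each shift was added to every member alike. The simulation therefore gives no error rate for the real lists, whose genes can vary together. Thresholds of 0.5 and 1 on the size of the statistic were used to count genes and have no error rate attached. Alternatives were the mean in place of the median, which was planned, and, chosen after seeing the data, inclusion of members at 0, random lists from all genes, the share of positive members, a minimum size of 0.1 and the stricter threshold of 1. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

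No test across samples was run, since 1 library per population leaves no spread between replicates to test against.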

Results

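Macrophages were collected from infarcted mouse hearts 3 days after the left anterior descending artery was tied off, and their RNA was sequenced. The populations are named by their level of Ly6C, a surface glycoprotein that is high on classical blood monocytes and on cells recently derived from them. The series holds 2 libraries, with 1 library of Ly6Chi macrophages and 1 library of Ly6Clo macrophages from C57BL/6 animals. The comparison asked how the transcriptomes of these populations differ. The values reported are the authors' signed comparison statistic and its rank for each of 23284 genes. The columns of values per library carry codes that match no sample label, so they were not used, and neither sign could be given to a population. Results are therefore given by side of the statistic, negative or positive, and Ly6c2 is used only as a landmark for the negative side. With 1 library per population there is no replicate check and no p-value. The depth behind each statistic was not analysed here, and small values of single genes are not interpreted.

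The genes of the Ly6C antigen are given first. Ly6c2, at chromosome 15 from 75108161 to 75112066 on mm10, had a statistic of -1.78 and rank 18 in the authors' deposited table. Its neighbour Ly6c1, from 75044018 to 75048920 on the same chromosome, had -0.53 and rank 991 in the authors' deposited table. The genes are close paralogs, and reads shared between them could be split by the counting. Both lay on the negative side.

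Across the authors' deposited table, 9399 genes had a positive statistic, 6903 a negative statistic and 6982 a statistic of exactly 0. Of the positive genes, 841 shared the smallest positive value, 2.42e-06. At a size of at least 0.5, 878 genes were positive and 230 negative. At a size of at least 1, 165 were positive and 15 negative. The largest values on the positive side therefore outnumbered those on the side of Ly6c2.

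The 12 leading genes of the positive side in the authors' deposited table encode a migratory chemokine receptor, a chemokine, antigen-presentation molecules, fibrillar collagens and lectin-like receptors. Ccr7, the receptor that guides dendritic cells to lymph nodes, had the highest statistic, 2.84, in the authors' deposited table. It lies on chromosome 11 from 99144199 to 99155077. Ccl22, a chemokine made by dendritic cells and macrophages, followed at 2.60 in the authors' deposited table. The MHC class II genes H2-Eb1, H2-Ab1 and H2-Aa stood at 2.52, 2.32 and 2.19 in the authors' deposited table, and Cd74, the invariant chain that escorts class II molecules, stood at 2.24. The G protein-coupled receptor gene P2ry10 had 2.39, the C-type lectin gene Mgl2 had 2.21 and the lectin-like receptor gene Klrb1b had 2.13 in the authors' deposited table. The fibrillar collagen genes Col1a1, Col3a1 and Col1a2 had 2.14, 2.03 and 1.99 in the authors' deposited table.

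The 12 leading genes of the negative side included monocyte products and genes of lipid uptake and lysosomes. Thbs1, which encodes the matricellular protein thrombospondin, had the lowest statistic, -1.89, in the authors' deposited table. It lies on chromosome 2 from 118111876 to 118127133. Chil3, a chitinase-like gene listed under its older symbol Chi3l3, had -1.86 in the authors' deposited table, while its close paralog Chil4, listed as Chi3l4, had -0.07. Gpnmb, a glycoprotein of lysosome-rich macrophages, had -1.56 and Cd177, a surface glycoprotein of neutrophils and monocytes, had -1.39 in the authors' deposited table. Fabp5, a fatty acid binding protein, had -1.33, and Cd36, a scavenger receptor for oxidised lipids, had -1.22 in the authors' deposited table. Spp1, which encodes osteopontin and lies on chromosome 5 from 104435111 to 104441053, had -1.18 and rank 110 in the authors' deposited table. The cathepsin gene Ctsl stood at -1.10, Slfn4 at -1.23, the small GTPase gene Rhov at -1.16 and the crystallin gene Crybb1 at -1.09 in the authors' deposited table.

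The identity lists parted by side. Of 17 classical monocyte genes, 14 were negative, with a median statistic of -0.43 computed from the authors' deposited table, below all 10000 random gene lists of the same size. Thbs1 and Chil3 led it, followed by Cd177 and by the proteoglycan gene Vcan at -0.90 in the authors' deposited table. Ccr2, the chemokine receptor that brings monocytes out of the bone marrow, went the other way at 0.21 in the authors' deposited table. Of 14 non-classical monocyte genes, 12 were positive, and their median of 0.24 stood at percentile 99.9 of random lists. Spn had 1.19, the fractalkine receptor gene Cx3cr1 had 1.14 and the B-cell and monocyte transcription factor gene Pou2f2 had 0.82, while Fabp4 had -0.90, in the authors' deposited table. Nr4a1, a nuclear receptor needed for non-classical monocytes, had 0.60 in the authors' deposited table. Of 11 pan-macrophage genes, 9 were negative, with a median of -0.22 at percentile 0.02. Fcgr1 had -0.79, Cd68 -0.68 and Lyz2 -0.53, and Adgre1, listed as Emr1, had -0.22 in the authors' deposited table. The 15 resident cardiac macrophage genes with a value other than 0 divided into 8 positive and 7 negative, and their median stood at percentile 34.1. However, 5 members reached 0.5 and none -0.5, and among genes of size 0.1 or more the list stood at percentile 99.8. Within that list Timd4 at 1.17, Lyve1 at 0.88, Fcna at 0.65 and Cd163 at 0.59 were the largest values in the authors' deposited table. Mrc1, the mannose receptor gene, had 0.05 in the authors' deposited table.

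**Figure D1:**
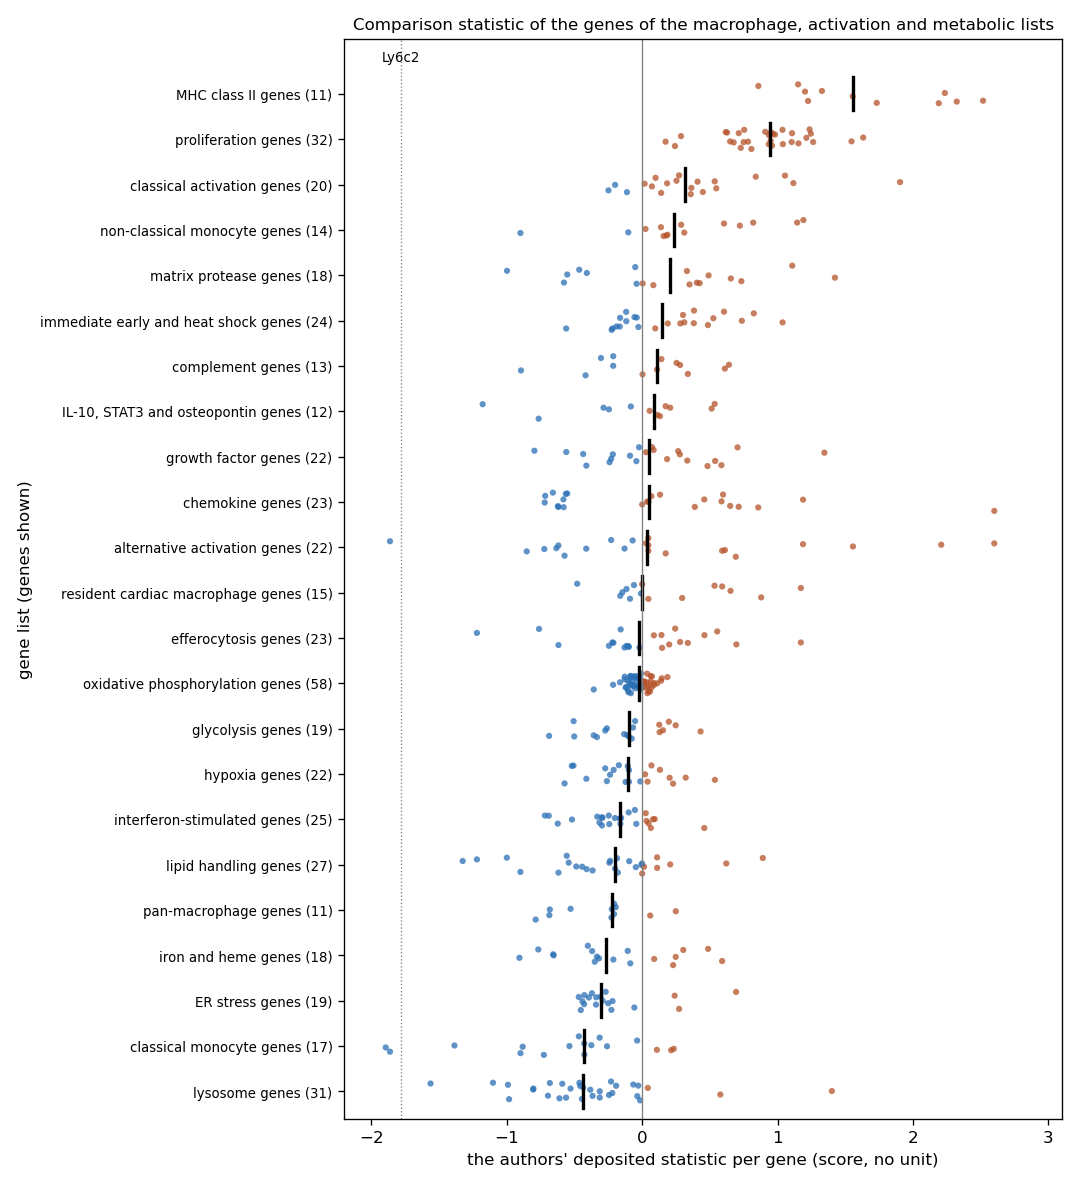
Each point is a gene of a list, placed on the x axis by the authors' deposited comparison statistic (a score without unit), with brown for positive and blue for negative values. Black bars are list medians, the dotted line marks Ly6c2 at -1.78, and the number after each list on the y axis is the count of genes shown; the 11 MHC class II genes and the 32 proliferation genes all lie above 0, and 28 of 31 lysosome genes lie below it.

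Genes of antigen presentation and of cell division lay together on the positive side. All 11 MHC class II genes were positive at 0.5 or more, from H2-DMa at 0.86 to H2-Eb1 at 2.52 in the authors' deposited table. Their median of 1.55 lay above all 10000 random lists. All 32 proliferation genes were positive and 29 of them reached 0.5, with a median of 0.94, above all 10000 random lists. Fibroblast and dendritic cell markers lay on the same side, with medians of 1.30 and 1.20, and pan-macrophage genes on the other, with a median of -0.22. The proliferation antigen gene Mki67 had 1.63, the topoisomerase gene Top2a 1.55, the cyclin gene Ccna2 1.26 and the tubulin-binding stathmin gene Stmn1 1.25 in the authors' deposited table.

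Inflammatory genes lay mainly on the positive side and interferon-stimulated genes mainly on the negative side. Of 20 classical activation genes, 17 were positive, with a median of 0.32, above all 10000 random lists. Dendritic cell and fibroblast markers, with medians of 1.20 and 1.30, lay on the same side. The cytokine genes Il12b, Il6 and Il1b had 1.90, 1.12 and 1.05 and the costimulatory receptor gene Cd40 had 0.84 in the authors' deposited table. Tnf had 0.25 and Nos2, the inducible nitric oxide synthase gene, had -0.11 in the authors' deposited table. Of 25 interferon-stimulated genes, 18 were negative, with a median of -0.16, below all 10000 random lists. The antiviral genes Rsad2 and Oasl1 had -0.72 and -0.69, the transcription factor gene Irf7 had -0.62 and Isg15 had -0.52 in the authors' deposited table.

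Alternative activation genes did not share a side. Of 22 genes, 12 were positive and 10 negative, and the median of 0.04 stood at percentile 76.3. Among genes of size 0.1 or more the list stood at percentile 7.39, also inside the band. Ccl22, Mgl2 and the transcription factor gene Irf4, at 1.56, lay on the positive side, and Chil3 on the negative side, in the authors' deposited table. Arg1, the arginase gene, had -0.57, Il10 had 0.17 and Tgfb1 had -0.23 in the authors' deposited table. The 23 chemokine genes also divided, with 14 positive and 9 negative and a median of 0.05 at percentile 83.1. All 9 negative chemokine genes were at -0.5 or below, among them the monocyte attractants Ccl7 at -0.72 and Ccl2 at -0.66 in the authors' deposited table. Ccl22, Ccl17 at 1.19, Ccl5 at 0.86 and Cxcl5 at 0.71 were on the other side in the authors' deposited table, and Ccl6 stood at -0.72. Of 12 genes of IL-10 signalling, STAT3 and osteopontin, 7 were positive, with a median of 0.08 at percentile 88.9 and a mean of the opposite sign, -0.07. Spp1 led that list, followed by Lgals3, the galectin-3 gene, at -0.76, Socs3 at 0.54 and Bcl3 at 0.51, and Mertk, an efferocytosis receptor gene, had -0.25 in the authors' deposited table.

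Lysosomal and lipid genes lay with Ly6c2. Of 31 lysosome genes, 28 were negative and 12 reached -0.5, with a median of -0.44, below all 10000 random lists. Gpnmb and Ctsl led, with the cathepsin gene Ctsb at -0.99 in the authors' deposited table. Ctsk, which encodes the collagen-degrading cathepsin K, was an exception at 1.40 in the authors' deposited table. Of 27 lipid handling genes, 20 were negative, with a median of -0.20, below all 10000 random lists. Fabp5, Cd36, the lipid droplet gene Plin2 at -1.0 and Fabp4 at -0.90 were its largest values in the authors' deposited table. Endothelial markers, which share Fabp4 with the lipid list, and pan-macrophage genes lay on the same side, with medians of -0.19 and -0.22. Of 18 iron and heme genes, 12 were negative, with a median of -0.27, below all 10000 random lists. The heme oxygenase gene Hmox1 had -0.91, the ferritin genes Ftl1 and Fth1 had -0.77 and -0.66, and the metal transporter gene Slc11a1 had -0.65 in the authors' deposited table. Of 19 ER stress genes, 16 were negative, with a median of -0.31, below all 10000 random lists, and the chaperone genes Hspa5, Calr and Dnajb9 had -0.47, -0.45 and -0.44 against 0.69 for Herpud1 in the authors' deposited table.

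Glycolysis and hypoxia genes had smaller negative medians. Of 19 glycolysis genes, 13 were negative, with a median of -0.10 at percentile 0.475, though at percentile 8.16 when only genes of size 0.1 or more were kept. Hk3 had -0.69, Pkm, listed as Pkm2, had -0.51, Pfkfb3 had -0.50 and Hk2 had 0.43 in the authors' deposited table. Of 22 hypoxia genes, 14 were negative, with a median of -0.10 at percentile 0.06, while their share of positive members stood at percentile 2.54, inside the band. Arg1 led, with Ddit4 at 0.54, Hif1a at -0.52 and Mxi1 at -0.51, and Vegfa, the main angiogenic growth factor gene, had -0.41 in the authors' deposited table. All 58 oxidative phosphorylation genes were under 0.5 in size, with a median of -0.02 at percentile 4.17, and Ndufa4 had the largest value, -0.36, in the authors' deposited table.

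Tissue-repair lists were mixed. Of 18 matrix protease genes, 11 were positive, with a median of 0.21 at percentile 99.9, while their share of positive members stood at percentile 60.8. Fibroblast markers and smooth muscle and pericyte markers, with medians of 1.30 and 0.31, lay on the same side. Mmp9 at 1.42, Mmp25 at 1.11 and Mmp12 at 0.73 were positive and Mmp8 at -1.0 was negative in the authors' deposited table. The 22 growth factor genes held 12 positive and 10 negative values, with a median of 0.05 at percentile 84.0. Pdgfb had 1.35, Inhba -0.80, Bmp2 0.70 and Vegfc 0.59 in the authors' deposited table. Of 23 efferocytosis genes, 11 were positive and 12 negative, with a median of -0.02 at percentile 13.7. Cd36, Timd4, the lipoprotein receptor gene Lrp1 at -0.76 and the receptor tyrosine kinase gene Axl at 0.70 were furthest from 0 in the authors' deposited table. Of 13 complement genes, 8 were positive, with a median of 0.11 at percentile 94.5, and Cfb had -0.89, C1s 0.61 and C3 -0.42 in the authors' deposited table. Of 24 immediate early and heat shock genes, 13 were positive, with a median of 0.14 at percentile 99.7. Egr3 had 1.04, Egr1 0.82, Btg2 0.74 and Nr4a1 0.60 in the authors' deposited table. That placement rests on the sizes, since the share of positive members stood at percentile 36.6.

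Markers of other cell types were placed unevenly. All 15 dendritic cell genes were positive and 10 reached 0.5, with a median of 1.20, above all 10000 random lists. Ccr7, Ccl22 and the actin-bundling gene Fscn1, at 1.8, led in the authors' deposited table. Ccl22 is shared with the alternative activation and chemokine lists, and macrophages can also express list members such as Itgax. The members Flt3 and Zbtb46 had 1.56 and 1.45 in the authors' deposited table, while 5 members stayed under 0.5. All 17 fibroblast genes were positive and 16 reached 0.5, with a median of 1.30, above all 10000 random lists. Besides the collagens Col1a1, Col3a1 and Col1a2, the fibroblast receptor gene Pdgfra had 0.92 in the authors' deposited table. All 10 smooth muscle and pericyte genes with a value other than 0 were positive, with a median of 0.31 at percentile 99.9, led by Cspg4 at 0.89, Pdgfrb at 0.65 and Myh11 at 0.61 in the authors' deposited table. Of 16 cardiomyocyte genes, 14 were positive, with a median of 0.16 at percentile 99.5, led by Tnnt2 at 0.53, Xirp2 at 0.46 and Actc1 at 0.27 in the authors' deposited table. Kept to genes of size 0.1 or more, the cardiomyocyte list stood at percentile 87.8. Of 14 endothelial genes, 11 were negative, with a median of -0.19 at percentile 0.01, led by Fabp4, which is also a macrophage gene, Kdr at -0.57 and Cdh5 at -0.46 in the authors' deposited table.

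Lymphoid and granulocyte markers did not stand apart. The medians of 11 T cell, 9 NK cell, 10 B cell and 14 neutrophil genes stood at percentiles 36.9, 44.8, 50.7 and 93.7. The largest neutrophil values were 1.21 for Il1r2, -1.0 for Mmp8 and 0.54 for S100a8 in the authors' deposited table. Among NK cell genes Ccl5 and Klrk1, at 0.86 and 0.84, were the largest values in the authors' deposited table. The 5 mast cell, basophil and eosinophil genes with a value had a median of 0.16 at percentile 93.0, and Kit led at 1.70 in the authors' deposited table. However, 8 of the 13 members in the table had a statistic of exactly 0. With these included, the list stood at percentile 40.9 of random lists from all genes. The medians of 5 erythroid and 9 platelet genes stood at percentiles 46.1 and 37.3, and the platelet chemokine gene Ppbp had -1.01 in the authors' deposited table. Of the 37 lists with a percentile, 10 stood at or above percentile 97.5 and 10 at or below 2.5. Lists of randomly drawn genes would put 1.85 outside these bounds. Genes of a real list can vary together and some lists overlap, so that number is not an error rate for these lists. These percentiles describe the 2 libraries and carry no replicate error, and they were not matched on expression level.

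**Figure D2:**
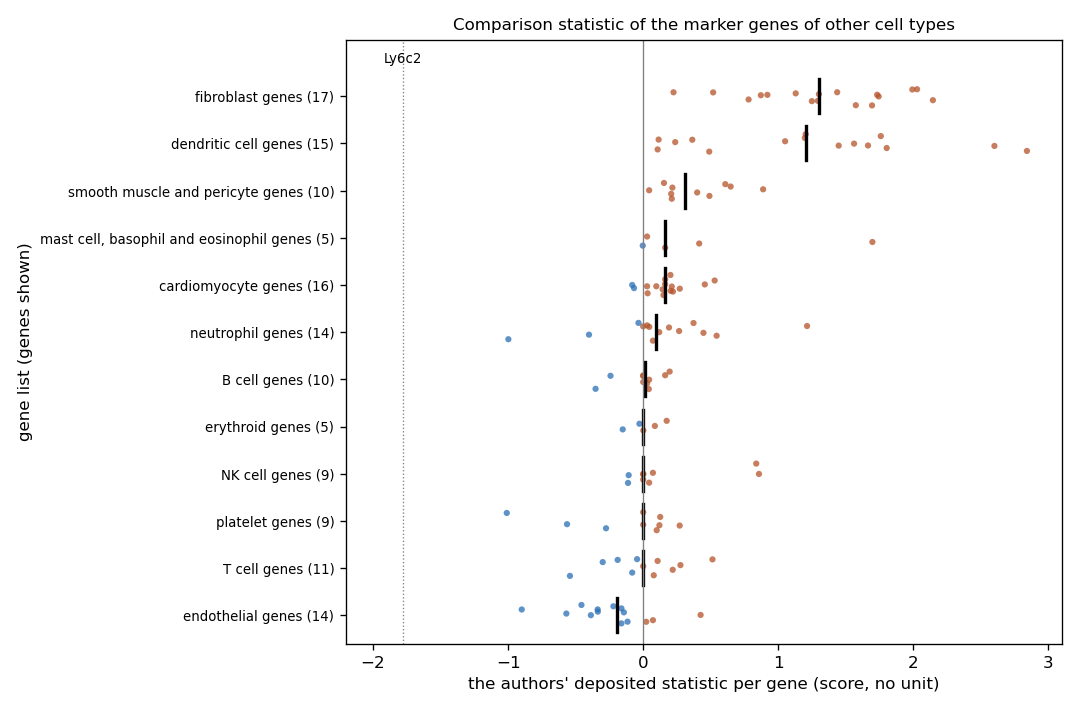
Each point is a marker gene of another cell type, placed on the x axis by the authors' deposited comparison statistic (a score without unit), with brown for positive and blue for negative values, black bars for list medians and a dotted line at Ly6c2. The y axis names each list and the count of genes shown; all 17 fibroblast and all 15 dendritic cell genes lie above 0, and 11 of 14 endothelial genes lie below it.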

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

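No paired analysis was possible because each population has 1 library, and leaving out a library leaves no comparison. All alternatives except the mean of the list were chosen after seeing the data. Planned changes to the pseudocount, the filter on low values, the scaling of the libraries, the 4-fold threshold and the weighted ranking of named genes were not run, since they need values per library. Random lists matched on expression were not run for the same reason. Raising the threshold from 0.5 to 1 changed the counts from 878 to 165 positive and from 230 to 15 negative genes. With the mean in place of the median, the mean of 36 of 37 lists lay inside the binomial interval of their median. The ER stress genes moved from -0.31 to -0.21, outside that interval. Inside it the sign could still change, as for the IL-10, STAT3 and osteopontin list, from 0.08 to -0.07. With members at 0 included, all 37 list medians stayed within that interval, but lists without a member at 0 could not move. For lists of 5 genes the interval was their full range, which a mean cannot leave. Random lists from all genes, which hold many zeros, brought 9 lists outside the band: alternative activation (percentile 97.7), chemokine (98.7), IL-10, STAT3 and osteopontin (98.5), complement (99.1), growth factor (98.6), neutrophil (97.9), efferocytosis (0.90), oxidative phosphorylation (0.03) and widely expressed reference genes (1.23). The zeros narrow the spread of the random medians, so these lists are not read as standing apart. By the share of positive members, matrix protease (60.8) and hypoxia genes (2.54) came inside the band, oxidative phosphorylation genes (0.145) went outside it, and immediate early and heat shock genes crossed to percentile 36.6. With a minimum size of 0.1, glycolysis (8.16) and cardiomyocyte genes (87.8) came inside the band and resident cardiac macrophage genes (99.8) went outside it. The cause of these moves was not tested. The other 33 lists that this minimum left with a percentile kept their place inside or outside the band. Moves within the band could be large. Alternative activation genes went from percentile 76.3 to 7.39, complement genes from 94.5 to 50.65 and B cell genes from 50.7 to 24.5.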

Other observations

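The tests in this part on fibroblast, dendritic cell and endothelial genes, and the gene families, were chosen after the leading genes had been seen; those on cardiomyocyte, lymphoid and neutrophil genes were chosen before their lists had been computed.

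Gene families picked by symbol after the lists had been computed gave the following values. Of 76 cytosolic ribosomal protein genes with a value other than 0, 67 were positive, with a median of 0.11, above all 10000 random lists, although none reached 0.5; Rps4x had the largest value, 0.29, in the authors' deposited table. Of 19 genes of the proton pump that acidifies lysosomes, 14 were negative, with a median of -0.24, below all 10000 random lists. Atp6v1h and Atp6v1c1 had -0.61 and -0.60 in the authors' deposited table, whereas Atp6v0d2, a subunit abundant in osteoclasts, had 0.58. Of 40 collagen genes, 35 were positive and 16 reached 0.5, with none at -0.5 or below. The 14 cathepsin genes had a median of -0.11 at percentile 0.57, with 5 positive and 9 negative members and Ctsk on the opposite side from Ctsl, Ctsb and Ctsd. The proton pump and cathepsin families share members with the lysosome list, and the collagens with the fibroblast list. Their values are therefore not separate support for those lists. Of 33 histone genes, 31 were positive, but their median of 0.03 stood at percentile 71.3.

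The sex-specific genes gave no large values. Xist, the transcript of the inactive X chromosome, had 0.24 in the authors' deposited table. The Y-linked genes Uty, Eif2s3y, Kdm5d and Ddx3y had -0.13, -0.11, -0.07 and -0.05, all on the opposite side from Xist. Genes of low abundance may have small scores whatever their ratio, so these values do not exclude a difference in sex between the libraries. Widely expressed reference genes had a median of -0.05 at percentile 8.26, and all 13 were under 0.5 in size.

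Fibroblast genes lay together on the positive side. Fibroblasts, or RNA released by them, in the library behind that side cannot be told apart from expression or uptake by the macrophages. Of the fibroblast list 100% was positive, and the statistic does not show which cells the RNA came from. A lower share of macrophages that raised every other heart cell type alike is argued against by the endothelial list, whose median stood at percentile 0.01. The test on the endothelial list was not set in advance, and it bears only on a rise of every type alike. A lower share of macrophages with uneven rises of other cells stays open. Pan-macrophage genes lay on the negative side, with a median at percentile 0.02. A carry-over of heart tissue in general stays open, since the lists of heart cells did not go together. The cardiomyocyte list stood at percentile 99.5 but at 87.8 among genes of size 0.1 or more. The endothelial list went the other way, and stood at percentile 0.02 with that minimum. A true difference between the populations was not tested and stays open.

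Dendritic cell genes and MHC class II genes also shared the positive side. Dendritic cells in the library behind that side cannot be told apart from expression of these genes by the macrophages. Of the dendritic cell list 100% was positive, and the statistic does not show which cells the RNA came from. A higher share of lymphoid and granulocytic cells of every kind alike was not seen but is not excluded. The lowest percentile among the T cell, B cell, NK cell and neutrophil lists was 36.9, under the bound of 75 set beforehand. Among genes of size 0.1 or more the 7 T cell and 4 B cell genes stood at percentiles 36.6 and 24.5. These values lie inside the band. Genes of low abundance may have small scores whatever their ratio, so these lists cannot decide the question. A rise in NK cells or neutrophils alone also stays open. With that minimum their lists stood at percentiles 95.05 and 95.1, from 4 NK cell and 9 neutrophil genes. Those 4 NK cell genes lay on both sides, with Ccl5 at 0.86 and Klrk1 at 0.84 against Txk and Eomes, both at -0.11, in the authors' deposited table. Ccl5 is also a member of the chemokine list. Of the 14 NK cell genes, 5 had a statistic of exactly 0, and without the minimum the NK cell list stood at percentile 44.8. A difference between the populations was not tested. Proliferation genes shared the same side, and whether they belong to macrophages or to these other cells was not tested.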
